A study of Mus musculus with 3 samples.

How the data were processed

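The 3 libraries were single-cell RNA-seq of unsorted lung cells from black 6 mice, 1 library per group: untreated controls called post-injury day 0, and lungs at day 14 and day 35 after bleomycin. Per the labels' protocols, lungs were minced and digested with collagenases II and IV at 5 mg/mL each, red blood cells were lysed, and suspensions were pooled before capture with the Chromium 3′ v3 kit and sequencing on an Illumina HiSeq. The number of mice in each pool is not given. Per the file headers, the deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode from Cell Ranger 7.0.1, and per the submitters' processing notes the genome build was mm10. Seurat is listed in the submitters' processing notes without a version or a role, and no file holds values made with it. The values were whole numbers, every retained barcode held at least 500 UMIs, and the 12 antibody hashtags that the files list held 0 UMIs in every library. All barcodes of a library carried 1 well suffix.

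Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. Before that limit, 1232 of 45146 barcodes at day 0, 3673 of 33799 at day 14 and 2885 of 24806 at day 35 exceeded 10% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.05 and left out. The caller set its threshold at a score of 0.777 at day 0 and called 0 of 45020 barcodes, so it did not work for that library. It called 18.3% of barcodes at day 14 and 13.8% at day 35. The libraries were therefore not treated alike in this step, and the alternative with doublets kept treats them alike. After all filters 43906, 24737 and 18724 barcodes were retained.

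Counts were scaled to 10000 per cell and log-transformed. A joint clustering used 2000 variable genes with the library as batch key, 30 principal components, 15 neighbours and the Leiden method at resolution 1, without integration. Clusters were named from markers of 27 cell types fixed before the data were examined. A name needed a marker among the cluster's 20 leading genes, a standardised marker score of at least 1 and at least 3 markers detected in 5% of its cells. A cluster stayed unnamed where another type held more of its 10 leading genes, or where it was shallow and none of those 10 was its own marker. These naming limits were set after the clusters were seen. So was a further rule that left clusters with at least 95% of their cells in 1 library unnamed. Classes are called "-like" throughout since they rest on transcripts alone. Macrophage-like cells pool alveolar and interstitial or monocyte-derived clusters.

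RNA of other lineages in a barcode was measured with genes specific to 1 of 6 lineages (epithelial, mesenchymal, endothelial, myeloid, B and T). Such genes had at least 50 CPM (counts per 1000000 counts of a class) in their lineage and 10 times the next lineage, learned over 4 rounds from the day 14 and day 35 libraries. A barcode's other-lineage RNA is its UMIs of genes specific to lineages other than its own, per 1000 UMIs. Barcodes with at most 10 per 1000 form the subset called low-mixture barcodes below. That limit was set after the data were seen.

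Raw counts were summed per library and class and expressed as CPM of the class total. A gene's ratio between 2 libraries carries the exact conditional binomial 95% interval of a ratio of Poisson counts. Shares carry exact Clopper-Pearson 95% intervals. With 1 library per group these intervals cover counting error only, not variation between mice or libraries, and no p-values or numbers of changed genes were computed. Ratios are called rises or falls where the interval excludes 1. Where a library held 0 UMIs, the ratio is a bound against a floor of 3 UMIs per library, written "at least".

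Each of 29 gene lists was scored by the median over its measured members of the log2 ratio of CPM with 1 added. Members with at least 20 UMIs over the compared libraries counted as measured. The interval of a median is the binomial order-statistic interval over members. Each median has its percentile among the medians of 10000 random lists of equal size and matched expression, a description of these libraries and not a test. The list of genes the study singled out (Csmd1, Cd248, Serpine2, Pi16) came partly from these libraries, so it is not independent evidence. The other lists were, for fibroblast-like cells, fibrillar and core matrix, collagen crosslinking and folding, myofibroblast, TGF-beta target, matrix protease and inhibitor, alveolar fibroblast and lipofibroblast, adventitial fibroblast and inflammatory fibroblast. For alveolar type 2-like cells they were surfactant and type 2 function, transitional epithelial, type 2 inflammatory and acute phase, and lipid and sterol synthesis. For macrophage-like cells they were scar-associated macrophage, resident alveolar macrophage, interstitial macrophage, alternative activation, and monocyte and neutrophil chemokine. For blood endothelial-like cells they were general capillary, aerocyte capillary and injury-associated endothelial. The MHC class II list was scored in the 3 classes other than fibroblast-like. The p53 target, proliferation, interferon response, dissociation stress, hypoxia and glycolysis, mitochondrially encoded and haemoglobin lists were scored in all 4. Some genes are in more than 1 list.

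Genes were named by a rule fixed before the data were examined. It took the 4 members with the largest absolute log2 ratio per list and comparison, and all genes the study singled out. It also took, per class, the 10 largest rises and 10 largest falls at day 14 over day 0 and at day 35 over day 14. These were drawn from genes with at least 50 UMIs and 20 CPM in the higher library and at least 10% of the highest class there, leaving out other classes' markers, unnamed gene models, ribosomal, mitochondrial, haemoglobin, immunoglobulin, Xist and Y-linked genes. Col1a1, Acta2, Sftpc, Krt8, Spp1, Chil3 and Car4 were followed in every library. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with B cell-like cells as a class that should lack the genes.

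Of 31053 gene identifiers in the files, 30934 (99.6%) were in GENCODE vM21, an annotation of GRCm38, which supplied coordinates. The authors' annotation release is not stated, and its build may differ in detail. Symbols are those of the files, 31017 of them distinct.

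Ratios and lists were tested on simulated Poisson counts drawn from the real class means. The intervals assume such counts, so coverage here checks the computation and not variation between cells, mice or libraries. For fibroblast-like cells at day 14 over day 0, over 13493 genes with 50 changed at each size, true folds of 0.25, 0.5, 2 and 4 gave median estimates of 0.246, 0.502, 1.93 and 3.97. Their intervals covered the truth for 92%, 98%, 96% and 96% of genes, and for 96.0% of unchanged genes. In that comparison a list of 20 genes raised by a log2 ratio of 1 had a median of 0.88 and percentile 100, over 13611 genes.

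Before the data were examined, 18 alternatives were fixed, which covered the barcode limits, doublets, clustering resolution, naming by a marker score per cell, scaling, the member minimum, the value added to CPM, thinning and weighting of cells. Another 5 were added after the data were seen: naming the clusters nearly all from 1 library, low-mixture barcodes alone, the share of named cells, and each macrophage group alone. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numba 0.67.0 and matplotlib 3.10.9 were used. Trimmed mean of M-values (TMM) and median-of-ratios factors were computed by direct implementations.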

Results

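Lungs of untreated black 6 mice and of mice at day 14 and day 35 after bleomycin, an antibiotic that breaks DNA and is given to rodents to scar the lung, were profiled as single cells without sorting. Each time point was 1 library with no replicate. The libraries held 178747799 UMIs in 45146 barcodes at day 0, 204134402 in 33799 at day 14 and 139964957 in 24806 at day 35. Median UMIs per barcode were 2892, 4170 and 3840, and median genes 1737, 1977 and 1816. The comparison of day 14 with day 0 asks which transcripts differ while scar tissue is forming. Day 35 asks which of them return toward the control level later. The series also concerns factors that act against scarring. Values after a fold or a share in parentheses are bounds of 95% intervals for counting error only.

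The libraries differed first in how many barcodes could be given a cell class. Unnamed clusters held 68.8% (68.4 to 69.2) of retained barcodes at day 0, 12.8% (12.3 to 13.2) at day 14 and 8.45% (8.06 to 8.86) at day 35. At day 0, 29645 barcodes, 67.5% (67.1 to 68.0) of those retained, lay in 4 clusters that held 127 barcodes at day 14 and 59 at day 35. Of these clusters, one with Inmt, Npnt and Lrat among its leading genes and one with Mmp3 and Sfrp4 scored highest for fibroblast markers, and held 2751 and 9925 day 0 barcodes. One with endothelial markers held 7109, and one led by Fabp1, Cidec and Krt79, genes of alveolar macrophages, held 9860. The unnamed day 0 barcodes carried 16.9 UMIs of other lineages per 1000, against 3.00 in B cell-like barcodes of that library. Named classes at day 0 therefore cover 13700 barcodes, and every ratio over day 0 is over that part of the library.

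Among retained barcodes, fibroblast-like cells made up 1.41% (1.31 to 1.53) at day 0, 2.41% (2.22 to 2.61) at day 14 and 2.69% (2.46 to 2.93) at day 35, from 621, 596 and 503 cells of 1 cluster. The direction of this change rested on the unnamed barcodes. As a share of named cells the values were 4.53%, 2.76% and 2.93%, and with the clusters nearly all from 1 library named too, the day 0 share was 30.3%. Macrophage-like cells made up 2.02% (1.89 to 2.16), 19.3% (18.8 to 19.8) and 28.7% (28.0 to 29.3). Blood endothelial-like cells made up 3.69% (3.52 to 3.87), 13% (12.6 to 13.4) and 10.5% (10.0 to 10.9), and B cell-like cells 3.42% (3.25 to 3.59), 19.7% (19.2 to 20.2) and 21.9% (21.3 to 22.5). T cell-like cells made up 1.21%, 7.56% and 8.49%. These rises shrank among named cells, where macrophage-like cells made up 6.47%, 22.1% and 31.3%, B cell-like cells 10.9%, 22.5% and 24.0% and T cell-like cells 3.87%, 8.66% and 9.28%. Blood endothelial-like cells made up 11.8%, 14.9% and 11.4% of named cells, so their day 35 rise rested on the unnamed barcodes. The unnamed clusters with alveolar macrophage and endothelial markers held 9860 and 7109 day 0 barcodes, against 887 and 1621 named cells. Counted with those classes, they would put both day 0 shares above the day 14 shares. Those barcodes were mixed, so neither direction at day 14 over day 0 is firm. Alveolar type 2-like cells, the makers of surfactant, fell from 2.72% (2.57 to 2.88) to 0.162% (0.116 to 0.22) and 0.166% (0.113 to 0.235), from 1195 to 40 and 31 cells. Only 65, 32 and 22 of them were low-mixture barcodes, with at most 10 UMIs of other lineages per 1000, so the size of the fall rested mostly on mixed day 0 barcodes. Among barcodes with little RNA of other lineages, the share of alveolar type 2-like cells was 0.678%, 0.155% and 0.125%.

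**Figure D1:**
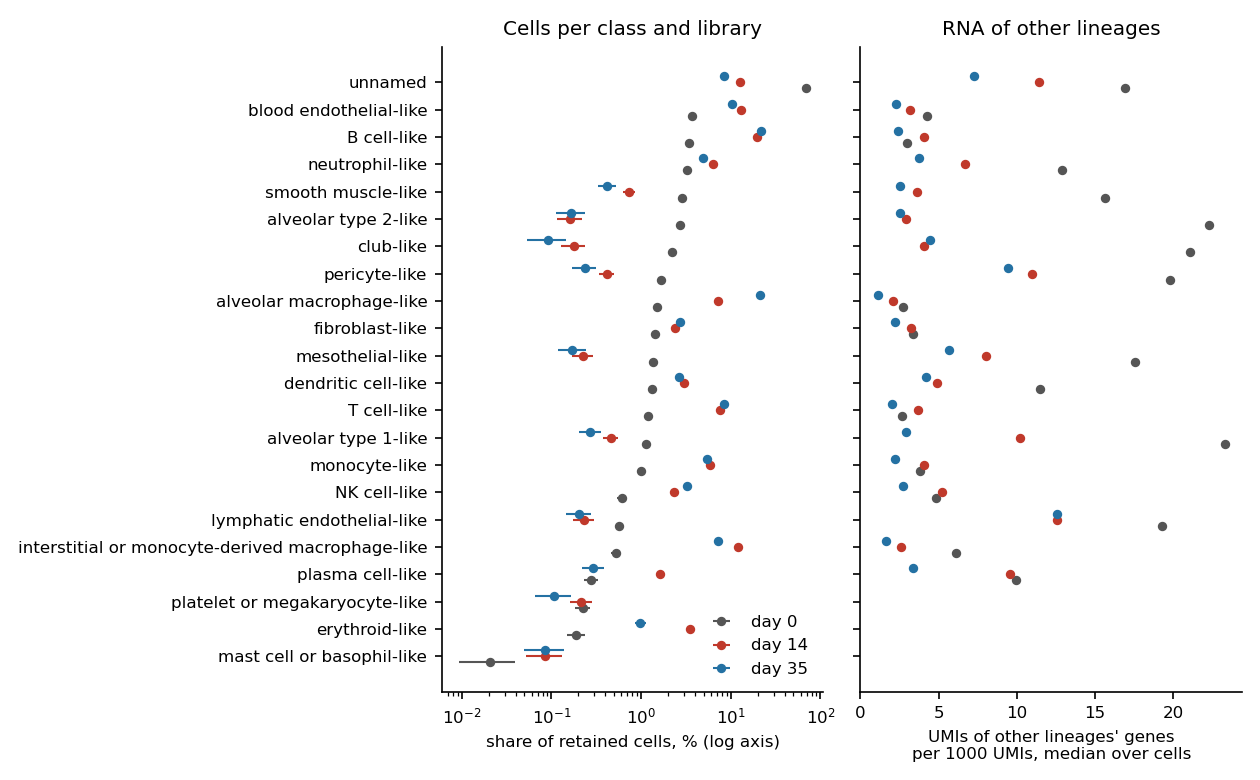
Share of retained barcodes per class on a log axis with exact 95% intervals (left) and UMIs of other lineages' genes per 1000 UMIs (right), for the day 0, day 14 and day 35 libraries. Unnamed clusters hold 68.8% of day 0 barcodes, and alveolar type 2-like barcodes at day 0 carry 22.3 UMIs of other lineages per 1000.

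In fibroblast-like cells at day 14, the matrix gene Tnc rose 25-fold (19.1 to 33.4) over day 0, and Cthrc1, a marker of scar-forming fibroblasts, rose 52.0-fold (25 to 130.3). Col1a1 (ENSMUSG00000001506, chromosome 11 from 94936224 to 94953042, forward strand of GRCm38) rose 2.46-fold (2.39 to 2.54), from 1103 to 2718 CPM. Acta2, the smooth muscle actin of contractile myofibroblasts, rose 4.74-fold (4.09 to 5.50). The acute-phase gene Saa3 rose 40.5-fold (29.8 to 56.4), and the cell-cycle gene Top2a 6.26-fold (3.92 to 10.5). Of the 10 genes with the largest falls, Muc13 fell 16.8-fold (11.2 to 26.6) and Trim69 10.3-fold (7.08 to 15.5).

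Most core matrix genes were higher at day 14 over day 0. The fibrillar and core matrix list had a median log2 ratio of 0.83 (0.49 to 1.11), at percentile 100 of matched random lists. Of its 27 members, 25 were higher and 2 lower, with 11 at least 2-fold higher and 0 at least 2-fold lower. Eln, which encodes elastin, rose 3.90-fold, and Fn1, fibronectin, 2.59-fold. In the collagen crosslinking and folding list, with a median of 0.47 (0.29 to 0.81), the prolyl hydroxylase P4ha3 rose 4.91-fold, the crosslinking enzyme Lox 3.52-fold and the collagen chaperone Fkbp10 2.34-fold. The myofibroblast list had a median of 1.41 (0.39 to 3.02), with 11 of 18 measured members at least 2-fold higher. Among them, the BMP antagonist Grem1, with 0 UMIs at day 0, was at least 17.9-fold higher. Spp1 reached 752 CPM at day 14, but B cell-like cells held 818 CPM, so its level there was background. In the matrix protease and inhibitor list, with a median of 0.17 (-0.37 to 1.02), Timp1 rose 7.83-fold, Adam12 6.25-fold and Ctsk 2.48-fold. The TGF-beta target list had a median of 0.28 (0.08 to 0.62), and its members Ctgf and Pmepa1 rose 1.87-fold and 1.78-fold. With the clusters nearly all from 1 library named too, mixed barcodes make up most of the day 0 base. The added clusters with fibroblast markers held 2751 and 9925 day 0 barcodes, with 14.7 and 17.1 UMIs of other lineages per 1000. Shifts in that setting, here and below, therefore cannot be told apart from effects of mixed RNA. The core matrix median was then 2.18. Col1a1 then rose by a log2 ratio of 2.75 instead of 1.30, and Acta2 by 0.32 instead of 2.22. Other single matrix genes then rose more, with log2 ratios that went from 2.95 to 4.50 for Timp1, 1.80 to 3.21 for Lox, 1.96 to 3.23 for Eln and 1.37 to 2.32 for Fn1, and from 2.09 to 3.12 for P4ha3, 1.2 to 2.32 for Fkbp10, 0.90 to 1.85 for Ctgf and 0.83 to 1.94 for Pmepa1.

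The inflammatory fibroblast list had a median log2 ratio of 0.73 (0.04 to 1.58), with 7 of 16 members at least 2-fold higher. Its siderophore-binding member Lcn2 rose 15.4-fold, and the cytokine Lif 3.25-fold. The neutrophil chemokine Cxcl5, with 1 UMI at day 0, was 75.5-fold (13.1 to 3023) higher. The proliferation list had a median of 1.99 (0.91 to 2.37) in the summed counts, with 9 of 14 members at least 2-fold higher, and Pclaf and Cdk1 rose 11.6-fold and 10.6-fold. Levels were low, with Top2a at 23.2 CPM in fibroblast-like and 40.4 CPM in B cell-like cells at day 14. With each cell thinned to 1000 UMIs, 2 members were left and their median was -0.29. Most of the rise of single cell-cycle genes also depended on naming. With cells named by marker score the log2 ratios were 0.59 for Pclaf, 0.97 for Cdk1 and 0.33 for Top2a, instead of 2.85, 2.45 and 2.36. With the clusters nearly all from 1 library named too they were 0.50, 0.80 and 0.09. Lcn2 likewise moved from 3.69 to 2.30 and 1.88. Outside the lists, rises included Kif26b at 57.7-fold, Ltbp2 at 8.37-fold, Kcnmb2 at 16.1-fold and Megf11 at 9.67-fold. With the clusters nearly all from 1 library named too, log2 ratios went from 5.37 to 4.04 for Kif26b, 3.02 to 4.33 for Ltbp2, 2.99 to 3.75 for Megf11 and 3.61 to 3.01 for Cxcl5.

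The alveolar fibroblast and lipofibroblast list, which holds genes of the fibroblasts beside the air sacs, had a median log2 ratio of -0.35 (-0.44 to -0.11) at percentile 0.02. This direction depended on the naming of day 0 clusters, since the median was 0.41 with cells named by marker score and 1.09 with the clusters nearly all from 1 library named too. The adventitial fibroblast list, of the fibroblasts around vessels and airways, had a median of -0.19 (-0.40 to 0.32). Its member Il33 rose 1.71-fold, a log2 ratio that went from 0.77 to 1.99 with those clusters named. Among the 10 largest falls were also Gipc2 at 8.82-fold, Efna2 at 6.31-fold, Pde4c at 6.17-fold and Nup210l at 5.72-fold. These falls and that of Muc13 were smaller under both naming changes. With the marker score and with the clusters nearly all from 1 library named too, log2 ratios were -3.04 and -2.40 for Muc13, instead of -3.80. They were -2.25 and -1.88 for Gipc2, -1.64 and -1.23 for Efna2, -1.76 and -1.14 for Pde4c, and -1.86 and -1.46 for Nup210l. Per 1000 UMIs, fibroblast-like barcodes held 3.37 of other lineages at day 0, 3.22 at day 14 and 2.18 at day 35.

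At day 35 over day 0, Tnc remained 10.5-fold (7.89 to 14.3) higher and Cthrc1 9.15-fold (4.03 to 24.3) higher. Grem1 was at least 65.8-fold higher. Col1a1 was 1.35-fold (1.30 to 1.41) higher, at 1494 CPM. Acta2 stood at 43.1 CPM against 39.0 at day 0, a ratio of 1.1 (0.888 to 1.37) whose interval includes 1. That return to the control level depended on naming, since the log2 ratio of Acta2 was -0.49 with the marker score and -1.68 with the clusters nearly all from 1 library named too, instead of 0.14. With the marker score, log2 ratios went from 0.44 to 1.04 for Col1a1, 2.46 to 1.56 for Cthrc1 and 5.16 to 3.97 for Grem1. With those clusters named, they went from 0.44 to 1.93 for Col1a1, 3.27 to 3.86 for Tnc, 1.22 to 2.34 for Col12a1 and 1.01 to 2.34 for Thbs2, and from 1.40 to 2.45 for P4ha3, 0.76 to 1.76 for Ctgf and 0.77 to 2.42 for Mfap5. The fibrillar and core matrix list had a median log2 ratio of 0.63 (0.40 to 0.79) at percentile 100, with Col12a1 up 2.36-fold and Thbs2 2.06-fold. With the clusters nearly all from 1 library named too, it was 2.08. Medians were 0.41 (0.14 to 0.62) for crosslinking and folding, where P4ha3 was 2.97-fold higher, and 0.65 (0.11 to 2.37) for the myofibroblast list. For protease and inhibitor genes the median was 0.23 (-0.06 to 0.89), with Ctsk 2.97-fold higher. For TGF-beta targets it was 0.15 (-0.10 to 0.41), with Ctgf 1.70-fold higher. The inflammatory list had a median of 0.13 (-0.19 to 0.51). The adventitial list stood at 0.42 (0.28 to 0.62) and percentile 100, with Dpp4 2.25-fold and Mfap5 1.71-fold higher. The alveolar and lipofibroblast list stood at -0.56 (-0.93 to -0.47), again turned by naming, to 0.23 with the marker score and 0.71 with the clusters nearly all from 1 library. Within it the amino acid transporter Slc7a10 was 3.70-fold lower and lipoprotein lipase Lpl 2.52-fold higher. Their log2 ratios shrank from -1.78 and 1.33 to -1.06 and 0.48 with the marker score, and to -0.22 and 0.16 with the clusters nearly all from 1 library.

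Between day 14 and day 35, Acta2 fell 4.29-fold (3.59 to 5.15) and its partner Tagln 3.95-fold (3.36 to 4.68), while Saa3 fell 27.3-fold (19.6 to 39.1) and Lcn2 7.08-fold (4.99 to 10.4). With doublets kept the log2 ratio of Saa3 was -4.0 instead of -4.65. Cthrc1 fell 5.68-fold (4.04 to 8.21), Lox 2.63-fold and Tnc 2.38-fold. Grem1 rose a further 3.67-fold (2.62 to 5.2), a log2 ratio of 1.77 that was 1.09 with doublets kept and 0.69 with the marker score, and the small proteoglycan Dcn rose 1.77-fold. The myofibroblast list had a median log2 ratio of -0.64 (-1.24 to 0.64), with 6 members at least 2-fold lower and 3 at least 2-fold higher. The inflammatory list had a median of -0.67 (-1.29 to -0.15), and the core matrix list -0.15 (-0.49 to 0.16). The other matrix medians were -0.11 (-0.52 to 0.15) for crosslinking and folding, -0.02 (-0.19 to 0.39) for proteases and inhibitors, where Timp1 fell 3.28-fold, by a log2 ratio of -2.58 with the marker score instead of -1.71, and -0.19 (-0.53 to 0.07) for TGF-beta targets. The adventitial list had a median of 0.60 (0.28 to 0.82) at percentile 100, and its member Scara5 rose 2.08-fold. At resolution 2, a fibroblast cluster led by Ebf2 and Scara5, with Pi16 among its leading genes, held 580, 374 and 386 cells in the 3 libraries. Another, led by Slit2 and Robo2, held 203, 226 and 119. Ratios in fibroblast-like cells may therefore also compare different mixes of cells. The alveolar and lipofibroblast list stood at -0.20 (-0.55 to -0.05), with Cxcl14 down 2.52-fold.

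Rises at day 35 over day 14 outside the lists included Tenm2 and Ibsp, which had no UMI at day 14 and were at least 58.0-fold and at least 43.5-fold higher. The Tenm2 rise nearly vanished with cells named by marker score, where its log2 ratio was 0.25, and was 3.83 at resolution 0.5 instead of 5.04. The glutamate receptor gene Grm7 rose 7.81-fold (4.84 to 13.2), Il1rapl1 5.61-fold (4.39 to 7.24) and Gap43 7.64-fold. The transcription factor gene Tbx20 rose 10.5-fold and the BMP receptor gene Bmpr1b 5.19-fold. Muc13, among the largest falls at day 14, rose 13.2-fold (8.64 to 21.2).

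The genes the study singled out in fibroblasts were Csmd1 (ENSMUSG00000060924, chromosome 8 from 15892537 to 17535586, reverse strand), Cd248 (ENSMUSG00000056481, chromosome 19 from 5068078 to 5070682, forward strand), Serpine2 (ENSMUSG00000026249, chromosome 1 from 79794197 to 79861180, reverse strand) and Pi16 (ENSMUSG00000024011, chromosome 17 from 29317680 to 29330593, forward strand), placed on GRCm38. They encode a complement regulator, a surface protein of mesenchymal cells, a protease inhibitor and a secreted peptidase inhibitor. They were chosen partly on these libraries. As a list they had a median log2 ratio of 0.62 (-0.15 to 1.55) at day 14 over day 0, 0.99 (0.68 to 1.27) at day 35 over day 0 and 0.37 (-0.47 to 1.01) at day 35 over day 14. In summed counts of fibroblast-like cells, Csmd1 rose 2.58-fold (2.41 to 2.75) at day 14 and 2.42-fold (2.24 to 2.60) at day 35. Serpine2 rose 2.94-fold (2.71 to 3.19) and 2.13-fold (1.93 to 2.34). From day 14 to day 35 they fell 1.07-fold and 1.38-fold. Cd248 and Pi16 had ratios of 0.904 (0.817 to 0.999) and 0.924 (0.874 to 0.976) at day 14 over day 0. At day 35 Cd248 was 1.60-fold (1.45 to 1.77) and Pi16 1.87-fold (1.77 to 1.97) higher than at day 0, and they rose 1.78-fold and 2.02-fold from day 14. The mix of fibroblast clusters differed between the libraries at resolution 2, as given above, and its part in these ratios was not tested. With the clusters nearly all from 1 library named too, the log2 ratios at day 14 over day 0 were 2.94 for Csmd1, 2.74 for Serpine2, 1.48 for Cd248 and 1.29 for Pi16. At day 35 over day 0 they went from 1.27 to 2.90 for Csmd1, 1.08 to 2.31 for Serpine2, 0.68 to 2.35 for Cd248 and 0.90 to 2.35 for Pi16. In low-mixture barcodes the ratio of Csmd1 at day 35 over day 14 turned to a log2 value of 0.03.

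After thinning each cell to 1000 UMIs, 3.44% (2.14 to 5.21) of fibroblast-like cells held a Csmd1 UMI at day 0, 12.4% (9.88 to 15.4) at day 14 and 14.5% (11.5 to 17.9) at day 35. In B cell-like cells the Csmd1 share was 0 of 1480 cells at day 0, which allows up to 0.249%, then 0.481% and 0.178%. The Cd248 share was 11.5% (9.06 to 14.3), 11.2% (8.80 to 14.1) and 20.1% (16.6 to 23.9), against 0.270%, 0.105% and 0.153% in B cell-like cells. Serpine2 was found in 10.3% (8.03 to 13), 17.9% (14.9 to 21.2) and 13.1% (10.2 to 16.3), against 0.541%, 0.795% and 0.0763%. Pi16 was found in 25.7% (22.3 to 29.4), 29.3% (25.6 to 33.2) and 37.3% (33.1 to 41.8), against 0.676%, 0.691% and 0.509%. Cells below 1000 UMIs were left out, 11, 9 and 5 fibroblast-like cells. Median UMIs before thinning were 8798, 7605 and 5853 in fibroblast-like and 4909, 2951 and 2668 in B cell-like cells. Unthinned shares in fibroblast-like cells were 10.1%, 23.0% and 21.5% for Csmd1 and 35.7%, 39.8% and 43.5% for Cd248. They were 39.9%, 53.7% and 36.4% for Serpine2 and 49.6%, 46.5% and 56.3% for Pi16.

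**Figure D2:**
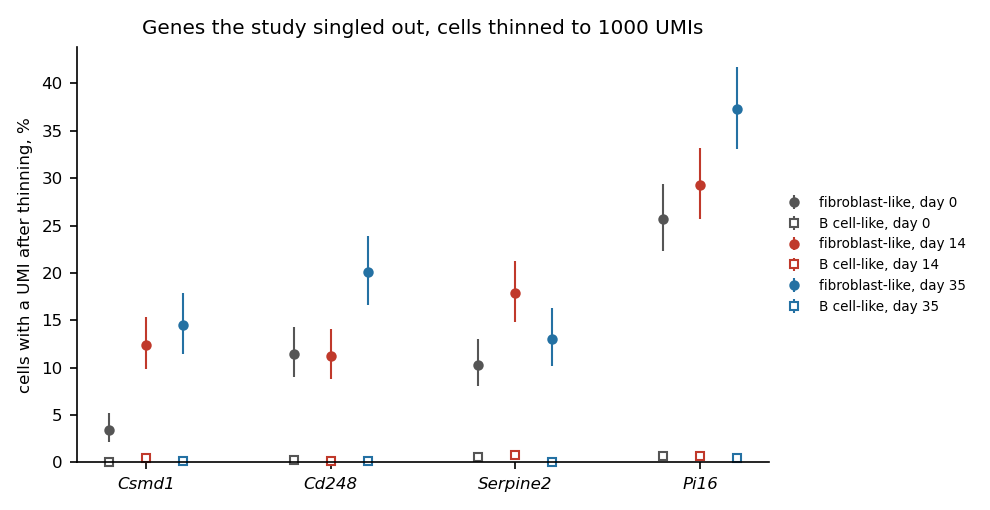
Share of fibroblast-like and B cell-like cells with at least 1 UMI of Csmd1, Cd248, Serpine2 and Pi16 after thinning to 1000 UMIs, at day 0, day 14 and day 35, with exact 95% intervals. The Csmd1 share in fibroblast-like cells is 3.44% at day 0 and 14.5% at day 35, and B cell-like shares are all under 1%.

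In macrophage-like cells at day 14, Spp1 (ENSMUSG00000029304, chromosome 5 from 104435118 to 104441050, forward strand of GRCm38), a secreted glycoprotein of macrophages in scars, rose 31.5-fold (30.3 to 32.9) over day 0, from 213 to 6713 CPM. Arg1, an enzyme of alternatively activated macrophages, rose 47.7-fold (34.3 to 68.6), and the elastase Mmp12 19.5-fold (17.7 to 21.6). The interferon-induced gene Ifit1 rose 8.65-fold (5.44 to 14.7), a log2 ratio of 2.54 that was 1.33 with cells named by marker score. The lipid-handling genes Fabp1 and Cidec of resident alveolar macrophages fell 7.38-fold (6.97 to 7.81) and 6.67-fold (6.26 to 7.10), and the scavenger receptor Cd163 fell 5.41-fold (4.80 to 6.09). Chil3 (ENSMUSG00000040809, chromosome 3 from 106147554 to 106167564, reverse strand) fell 1.47-fold (1.45 to 1.48) and stood at 4992, 3403 and 5591 CPM in the 3 libraries. The class was made of different clusters over time: alveolar clusters gave 657 of 887 cells at day 0, 1783 of 4763 at day 14 and 4007 of 5366 at day 35, and 1 interstitial or monocyte-derived cluster gave 230, 2980 and 1359. The TMM log2 factors in this class were -0.22 at day 14 over day 0 and -0.28 at day 35 over day 0. These factors are subtracted, so log2 ratios in this class were higher under TMM scaling.

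The scar-associated macrophage list had 14 of 20 members at least 2-fold higher, 0 at least 2-fold lower and 3 lower by less. Its median log2 ratio was 1.92 (0.77 to 2.99), at percentile 100. It was 1.67 in alveolar clusters alone and 1.67 in the interstitial cluster alone. Each group also changed in make-up over time. At resolution 2, an interstitial cluster led by Ccl8, Ccl12 and C1qa held 436, 684 and 373 cells in the 3 libraries. Another, led by Mmp12, Apoe and Trem2, held 9, 1982 and 895. An alveolar cluster led by Ctsk and Spp1 held 23, 995 and 2456. Values for a group alone therefore still compare different mixes of cells. Syngr1, which encodes a vesicle protein, rose 27.2-fold. The resident alveolar macrophage list had a median of -0.72 (-1.54 to 0.03), with 7 of 17 members at least 2-fold lower, among them Krt79 at 7.03-fold and Ear1 at 4.66-fold. In alveolar clusters alone it was -0.20, and in the interstitial cluster alone 0.27 (-1.28 to 1.05). Its lowest member stood at -2.85 over the pooled class, -1.83 in alveolar clusters alone and -3.16 in the interstitial cluster alone. The pooled falls of Fabp1, Cidec, Krt79 and Ear1 were thus larger than any in alveolar clusters alone. The interstitial macrophage list had a median of -0.17 (-1.41 to 1.32), with 6 members at least 2-fold higher and 5 at least 2-fold lower. Its lipid carrier Apoe rose 5.12-fold, while Lyve1, a marker of macrophages along vessels, fell 4.10-fold and Folr2 2.89-fold. In the interstitial cluster alone the list stood at -1.90 (-3.11 to -0.41), and in alveolar clusters alone at 0.69 (-0.18 to 2.53).

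The alternative activation list had 3 of 14 members at least 2-fold higher and 4 at least 2-fold lower, including the lectin Cd209d at 8.63-fold. Its median log2 ratio was -0.40 (-1.41 to 1.65). It was -0.03 and -0.17 in the alveolar and interstitial clusters alone. Its member Arg1 is also in the scar-associated list. The monocyte and neutrophil chemokine list had a median of 0.43 (-0.62 to 0.88), with Ccl9 up 4.37-fold and Cxcl16 3.81-fold. The medians had opposite signs, with 0.62 (0.08 to 1.15) in alveolar clusters alone and -0.30 (-1.13 to 0.79) in the interstitial cluster alone. The MHC class II list, of antigen presentation, had a median of 0.15 (-0.10 to 0.26) over the pooled class. It was 0.01 (-0.16 to 0.15) in alveolar clusters alone but -0.96 (-1.36 to -0.29) in the interstitial cluster alone, with all 7 members lower. Outside the lists, the transcript AA467197 rose 24.1-fold, Mfge8, which bridges dying cells to phagocytes, 17.5-fold, the growth factor Nrg1 11.9-fold and Wfdc17 10.5-fold. With the marker score, log2 ratios went from 4.0 to 2.97 for Mfge8, 3.39 to 2.71 for Nrg1 and -3.90 to -3.27 for Dnah11. The transporter gene Slc36a2, with 3 UMIs at day 0, was 140.2-fold (47.9 to 680.2) higher, a log2 ratio with 1 added to each CPM of 4.98 that became 2.93 with cells named by marker score. The largest falls included Vwce at 42.4-fold, Cd209f at 21.2-fold, Dnah11 at 16.5-fold and Itgad at 11.4-fold.

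Relative to day 0, Spp1 at day 35 was 34.5-fold (33.1 to 35.9) higher, Syngr1 23.7-fold, Mmp12 10.1-fold and Arg1 8.87-fold. The scar-associated median log2 ratio was 1.57 (0.66 to 2.68) at percentile 100, and 1.70 and 2.01 in the alveolar and interstitial clusters alone. The interstitial list had a median of -1.53 (-1.94 to 0.15), with Cd163 6.72-fold and Pf4 4.10-fold lower. In alveolar clusters alone it was -0.23 (-0.68 to 1.38), and in the interstitial cluster alone -2.05 (-2.43 to -0.38). The MHC class II list had a median of -1.02 (-1.30 to -0.23), with H2-Eb1 2.46-fold and H2-Aa 2.33-fold lower, and medians of -0.51 and -1.6 in the alveolar and interstitial clusters alone. The resident alveolar list stood at -0.12 (-0.69 to 0.41), with Fabp4 2.5-fold higher and Fabp1 3.32-fold lower, and at 0.32 (-0.50 to 1.29) in the interstitial cluster alone. The chemokine list stood at -0.72 (-1.63 to 0.16), with Ccl12 7.34-fold lower, by a log2 ratio of -2.08 with the marker score instead of -2.72, and alternative activation at -0.46 (-2.03 to 0.47), with Mgl2 4.0-fold lower.

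Between day 14 and day 35, Spp1 stayed high and rose 1.09-fold (1.09 to 1.1), while Arg1 fell 5.38-fold (5.10 to 5.68), Mmp14 2.80-fold and Mmp12 1.93-fold. The scar-associated list had a median log2 ratio of -0.18 (-0.55 to 0.07) over the pooled class, but 0.08 (-0.13 to 0.23) in alveolar and 0.38 (0.10 to 0.53) in interstitial clusters alone, so neither group's median was below 0. The resident alveolar list had a median of 0.74 (0.56 to 0.85), with 16 of 17 members higher and 3 at least 2-fold higher. Rises included Ear1 at 2.81-fold, Cidec at 2.33-fold and the lipid regulator Pparg at 2.0-fold. That median was 0.13 in alveolar and 0.31 in interstitial clusters alone, with 13 and 14 of 17 members higher. The largest member rise was a log2 ratio of 1.48 over the pooled class, but 0.60 and 1.08 in those groups alone. The pooled rises of Ear1 and Cidec thus exceeded those in either group. Medians were -1.13 (-1.59 to -0.73) for chemokines, where Ccl8 fell 5.76-fold and Il1b 3.03-fold, with -0.99 in alveolar and -0.24 in interstitial clusters alone. The lowest chemokine member stood at -2.44 over the pooled class, but at -1.73 in alveolar and -1.43 in interstitial clusters alone. The MHC class II list stood at -1.12 (-1.37 to -0.14), beyond the -0.66 (-0.74 to 0.13) in alveolar and -0.64 (-0.80 to -0.27) in interstitial clusters alone. The alternative activation list stood at -0.21 (-2.19 to 0.68), with Ccl24 down 16.9-fold, by a log2 ratio of -3.09 with the marker score instead of -3.80, and Ccl17 4.86-fold, whose log2 ratio was -0.99 at resolution 2 instead of -2.19. The interstitial list had a median of -1.12 (-1.29 to -0.60), but -0.75 in alveolar clusters alone and 0.08 in the interstitial cluster alone. Saa3 fell 59.2-fold and Dcstamp, which drives cell fusion, 5.2-fold. Rises outside the lists included Mamdc2 at 3.79-fold, Egfem1 at 3.56-fold and the scavenger receptor Colec12 at 2.95-fold.

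In blood endothelial-like cells at day 14, Lrg1, a glycoprotein that modifies TGF-beta signalling, rose 7.55-fold (6.97 to 8.18) over day 0. The venule receptor Ackr1 rose 8.24-fold (5.56 to 12.7), the neurotrophin receptor Ntrk2 3.81-fold (3.42 to 4.25) and the basement membrane gene Col15a1 3.02-fold (2.62 to 3.48). Top2a rose 3.10-fold (2.69 to 3.58). Fibin, a gene of gas-exchange capillary cells, fell 1.73-fold (1.60 to 1.88), a log2 ratio of -0.78 that was -0.19 with the clusters nearly all from 1 library named too. The injury-associated endothelial list had a median log2 ratio of 0.62 (-0.14 to 1.24) at percentile 100. Of 17 measured members, 7 were at least 2-fold higher, 0 at least 2-fold lower and 5 lower by less. The aerocyte list, for the wide flat capillary cells of gas exchange, had a median of -0.17 (-0.32 to 0.10), and Emp2 fell 1.54-fold. The general capillary list had a median of 0.07 (-0.24 to 0.35), where Kit rose 1.44-fold and Cxcl12 1.27-fold. Car4 (ENSMUSG00000000805, chromosome 11 from 84957786 to 84966044, forward strand of GRCm38), a carbonic anhydrase of aerocytes, stood at 314, 264 and 306 CPM in the 3 libraries. Outside the lists, Lama1 rose 11.6-fold, Inhbb 10.8-fold, Csmd1 8.55-fold, Clca3a1 6.72-fold, Ankrd37 5.86-fold, Cmah 5.55-fold and Vcan 4.17-fold. The largest fall was that of Cfd at 36.6-fold (27.4 to 50.1), but it turned to a rise with a log2 ratio of 1.62, on 37 UMIs, where at most 5% mitochondrial UMIs were allowed. Other falls included Trim69 at 6.98-fold, Pde4c at 6.21-fold and Cytl1 at 3.58-fold. At resolution 2, a blood endothelial cluster led by Selp, Cytl1 and Slc6a2 held 585, 325 and 184 cells in the 3 libraries. Another, led by Lama1 and Scn3b, held 741, 2135 and 1460. Ratios in blood endothelial-like cells, here and below, therefore also compare different mixes of cells. With the clusters nearly all from 1 library named too, log2 ratios were -0.65 for Cytl1 instead of -1.81, and 1.02 for Vcan instead of 1.92. They went from 3.45 to 4.16 for Lama1, 2.55 to 3.18 for Clca3a1, 2.98 to 1.83 for Csmd1 and -4.69 to -3.27 for Cfd. In low-mixture barcodes the log2 ratio of Csmd1 was 4.62. The MHC class II list had a median of -0.17 (-0.39 to -0.03), which turned above 0 in 3 alternatives, to 0.15 with doublets kept, 0.04 at resolution 0.5 and 0.02 in low-mixture barcodes.

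Relative to day 0, Ntrk2 at day 35 was 4.65-fold (4.16 to 5.21) higher, Ackr1 3.51-fold (2.22 to 5.69), Lrg1 2.88-fold (2.62 to 3.17) and Col4a2 2.66-fold. The injury-associated list had a median log2 ratio of 0.14 (-0.01 to 1.33) at percentile 98.54, with 6 members at least 2-fold higher. The general capillary list had a median of 0.25 (-0.13 to 0.46), with Cxcl12 2.30-fold and Sema3c 1.40-fold higher, and the aerocyte list 0.03 (-0.08 to 0.16), with Prx 1.39-fold higher. The MHC class II list stood at -0.47 (-0.70 to 0.10), with H2-Eb1 1.63-fold lower, by a log2 ratio of -1.30 with the clusters nearly all from 1 library named too instead of -0.70.

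From day 14 to day 35, Lrg1 fell 2.62-fold (2.47 to 2.77), Ackr1 2.35-fold, Col15a1 1.71-fold and Vcan 5.61-fold, while Cxcl12 rose 1.80-fold (1.74 to 1.87) and Emp2 1.45-fold. The adhesion gene Selp fell 3.77-fold and the arterial connexin gene Gja5 3.72-fold. Median log2 ratios were -0.06 (-0.62 to 0.28) for the injury-associated list, 0.11 (-0.09 to 0.45) for general capillary genes, 0.21 (-0.07 to 0.47) for aerocyte genes and -0.25 (-0.49 to 0.13) for MHC class II genes.

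Alveolar type 2-like cells rest on 40 cells at day 14 and 31 at day 35, and their day 0 barcodes were mixed. Those held 22.3 UMIs of other lineages per 1000, against 2.89 and 2.55 later, so each fold over day 0 is followed by the fold in low-mixture barcodes, 65, 32 and 22 cells. At day 0, Xist and Y-linked transcripts shared a barcode 1.13 (0.869 to 1.43) times as often as if independent, against 0.297 (0.109 to 0.647) in fibroblast-like cells. At day 14 over day 0, Krt8 (ENSMUSG00000049382, chromosome 15 from 101996698 to 102004482, reverse strand of GRCm38), a keratin of epithelium in transition to type 1 cells, rose 6.24-fold (5.12 to 7.59), and 2.60-fold (2.03 to 3.33) in low-mixture barcodes. Its level was 60.7, 379 and 183 CPM over all barcodes of the 3 libraries. Lcn2 rose 9.57-fold, and 2.74-fold in low-mixture barcodes. The cytokine-like gene Retnla rose 5.79-fold and 39.4-fold, the mucosal chemokine Cxcl17 8.84-fold and 7.49-fold, and Clu 4.86-fold and 2.82-fold. With the marker score the log2 ratio of Cxcl17 was 2.33 instead of 2.93. The rise of Retnla depended on naming too, with a log2 ratio of 0.68 with cells named by marker score, against 2.53 over all barcodes and 5.26 in low-mixture barcodes. Sftpc (ENSMUSG00000022097, chromosome 14 from 70520949 to 70524081, reverse strand) stood at 33982, 75331 and 108427 CPM over all barcodes, but at 114804, 84827 and 129725 CPM in low-mixture barcodes, a ratio at day 14 over day 0 of 0.739 (0.729 to 0.749).

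The transitional epithelial list had a median log2 ratio of 0.61 (-0.53 to 1.88) at percentile 99.99. Of 18 measured members, 6 were at least 2-fold higher and 2 at least 2-fold lower. At day 35 over day 0 the list's median was 0.85 (0.30 to 1.47). There Areg, a ligand of the EGF receptor, was up 9.11-fold (7.22 to 11.5), and 4.98-fold in low-mixture barcodes. Both list medians are over all barcodes. Over the alternatives, low-mixture barcodes among them, they ranged from 0.19 to 0.68 and from 0.37 to 1.04. At day 35 over day 14 the list's median was 0.16 (-0.80 to 1.06), where Krt8 fell 2.07-fold (1.53 to 2.84) and Areg rose 3.06-fold (2.22 to 4.28). The largest rises there included genes expressed in macrophages, Mrc1 at 6.19-fold, Ccl6 at 5.01-fold and Ctsd at 3.89-fold, which were 1.36-fold, 1.1-fold and 1.40-fold in low-mixture barcodes, where Areg rose 3.26-fold. With doublets kept the log2 ratios of Mrc1, Ccl6 and Ctsd were 1.90, 0.63 and 0.37 instead of 2.60, 2.32 and 1.96, and with the marker score 1.11 for Mrc1 and 1.51 for Ccl6. The type 2 inflammatory and acute phase list had medians of 1.42 (-0.08 to 2.61), 1.13 (-1.74 to 2.17) and -0.20 (-1.08 to 0.38) in the same order. Its medians over day 0 rest on all barcodes, mixed ones included. Retnla fell 19.6-fold (12.5 to 32.3) and Lcn2 2.11-fold from day 14 to day 35. With at most 5% mitochondrial UMIs the log2 ratio of Lcn2 was -0.26 instead of -1.08, and that of Retnla with the marker score was -2.48 instead of -4.27. The surfactant and type 2 function list had medians of 1.27 (1.03 to 1.46) and 1.19 (1.03 to 1.59) over day 0, which turned to -0.18 and -0.06 in low-mixture barcodes, and 0.01 (-0.30 to 0.35) at day 35 over day 14. The lipid and sterol synthesis list turned likewise, from 0.75 (0.17 to 1.37) and 0.74 (0.33 to 1.46) to -0.14 and -0.28, and stood at -0.05 (-0.20 to 0.33) at day 35 over day 14. MHC class II medians, likewise over all barcodes, were -0.25 (-1.23 to 0.15), 0.14 (-0.50 to 0.50) and 0.64 (0.27 to 0.76). H2-Eb1 rose 1.56-fold from day 14 to day 35.

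**Figure D3:**
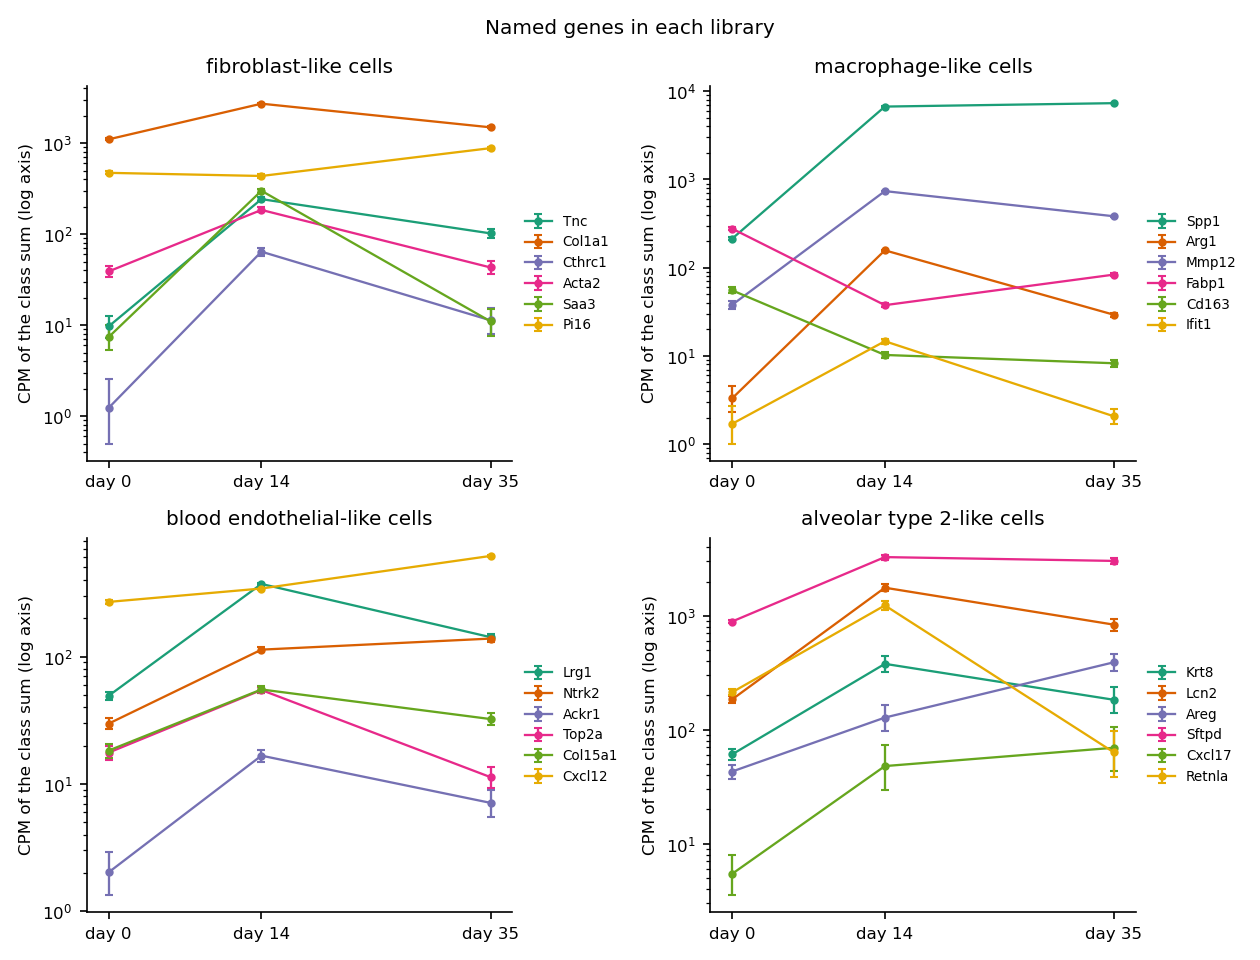
CPM in summed counts of each class against day, on a log axis, for 6 genes in each of 4 classes. Vertical bars are exact 95% intervals for counting error, and each point is 1 library.

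Lists scored in all 4 classes are given in the order day 14 over day 0, day 35 over day 0 and day 35 over day 14. The interferon response list in macrophage-like cells had median log2 ratios of 1.40 (0.61 to 2.07), 0.02 (-0.47 to 0.24) and -1.67 (-2.05 to -0.93), with 12 of 16 members at least 2-fold higher at day 14. The pooled values hide a split: in alveolar clusters alone the medians were 1.15, 0.31 (0.04 to 0.60) and -1.11, and in the interstitial cluster alone 0.78, -0.68 (-1.07 to -0.26) and -1.38. Rsad2 rose 6.26-fold at day 14, by a log2 ratio of 1.65 with the marker score instead of 2.39, and from there to day 35 Ifit1 fell 7.11-fold and Cxcl10 4.57-fold. In fibroblast-like cells the medians were 0.58 (0.17 to 0.98), 0.06 (-0.06 to 0.30) and -0.35 (-0.65 to -0.21), with Ifi44 up 4.30-fold and Zbp1 2.25-fold at day 14. The log2 ratio of Ifi44 was 0.49 with the marker score and 0.81 with the clusters nearly all from 1 library, instead of 1.72. The list medians were 0.14, 0.02 and -0.07 in blood endothelial-like cells and -0.32, -0.23 and 0.00 in alveolar type 2-like cells. Matched random lists in alveolar type 2-like cells had nearly the same medians, -0.28, -0.25 and -0.04.

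The proliferation list in blood endothelial-like cells had median log2 ratios of 1.31 (0.98 to 1.48), -0.29 (-0.60 to 0.12) and -1.67 (-1.81 to -0.99), with 11 of 15 members at least 2-fold higher at day 14. Cenpf rose 6.08-fold, by a log2 ratio of 1.5 with the clusters nearly all from 1 library named too instead of 2.35, and Ube2c 3.58-fold, and Ube2c then fell 7.77-fold. In fibroblast-like cells the later medians were 0.06 (-0.49 to 0.47) at day 35 over day 0 and -1.74 (-2.59 to -0.89) at day 35 over day 14, where Pclaf fell 8.96-fold. Medians were -0.27, -0.18 and 0.04 in macrophage-like cells and -0.88, -0.57 and -0.34 in alveolar type 2-like cells. Matched random lists in alveolar type 2-like cells had medians of -0.88, -0.59 and -0.06, so the first 2 values show no fall particular to proliferation. The value of -0.34 rests on 2 measured members. The macrophage groups alone had other signs than the pooled class at day 14 over day 0, with 0.08 (-0.16 to 0.48) in alveolar and 0.36 (0.06 to 1.04) in interstitial clusters, and at day 35 over day 14, with -0.25 (-0.35 to -0.01) and -0.54 (-0.68 to -0.23). The hypoxia and glycolysis list stood at 0.63 (0.33 to 0.95), 0.22 (-0.36 to 0.46) and -0.51 (-0.93 to 0.04) in macrophage-like cells, where the glycolytic genes Hk2 and Pgk1 rose 2.64-fold and 1.94-fold at day 14. In blood endothelial-like cells it stood at 0.24, 0.15 and -0.18, and Bnip3, of mitochondrial turnover in low oxygen, rose 2.42-fold at day 14. In fibroblast-like cells it stood at -0.16, -0.11 and -0.05, and in alveolar type 2-like cells at -0.18, 0.06 and -0.05. Matched random lists in alveolar type 2-like cells had medians of -0.22, -0.25 and -0.15. The p53 target list, of the response to DNA damage, had medians of 0.31, 0.22 and -0.02 in fibroblast-like and 0.14, 0.06 and -0.06 in macrophage-like cells. They were 0.21, 0.16 and -0.02 in blood endothelial-like and -0.18, 0.30 and 0.46 in alveolar type 2-like cells. In the latter class matched random lists had medians of -0.16, -0.20 and -0.05.

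The dissociation stress list, of early genes that tissue digestion switches on, had medians below 0 in each class at day 14 and day 35 over day 0. Its median log2 ratio in fibroblast-like cells was -0.45 (-0.62 to -0.25) at day 14 and -0.52 (-0.68 to -0.39) at day 35 over day 0, with Atf3 down 2.09-fold at day 14, a log2 ratio of -1.06 that was -0.32 with the clusters nearly all from 1 library named too. In macrophage-like cells the values were -0.47 (-0.71 to -0.33) and -1.0 (-1.25 to -0.63), with Egr1 down 3.84-fold at day 35, and -0.58 at day 35 over day 14, against -0.34 in alveolar and -0.15 in interstitial clusters alone. In blood endothelial-like cells they were -0.49, -0.25 and 0.21, with Btg2 down 2.0-fold at day 14. In alveolar type 2-like cells they were -0.69, -0.75 and -0.05. The mitochondrially encoded list had medians at day 14 over day 0 of 0.24 in fibroblast-like, 0.23 in macrophage-like and 0.22 in blood endothelial-like cells.

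Haemoglobin transcripts, which belong to red blood cells, moved apart between classes and days. Their median log2 ratio at day 14 over day 0 was 1.72 (1.34 to 2.16) in fibroblast-like, 0.91 (0.77 to 0.96) in macrophage-like, 0.26 (-0.06 to 0.45) in blood endothelial-like and -3.29 (-4.07 to -3.10) in alveolar type 2-like cells. The day 35 over day 0 medians were -1.83, -0.82, -0.25 and -4.34 in the same order. The alveolar type 2-like values are over mixed day 0 barcodes, with 22.3 UMIs of other lineages per 1000. The day 14 direction in fibroblast-like cells turned to -0.28 with the marker score and -0.41 with the clusters nearly all from 1 library named too. In macrophage-like cells it turned to -0.43 at resolution 0.5, -0.78 at resolution 2, -1.01 with the marker score and -0.54 in the interstitial cluster alone. At day 35 over day 0, doublets kept turned it to 0.33 in fibroblast-like and 0.25 in blood endothelial-like cells.

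**Figure D4:**
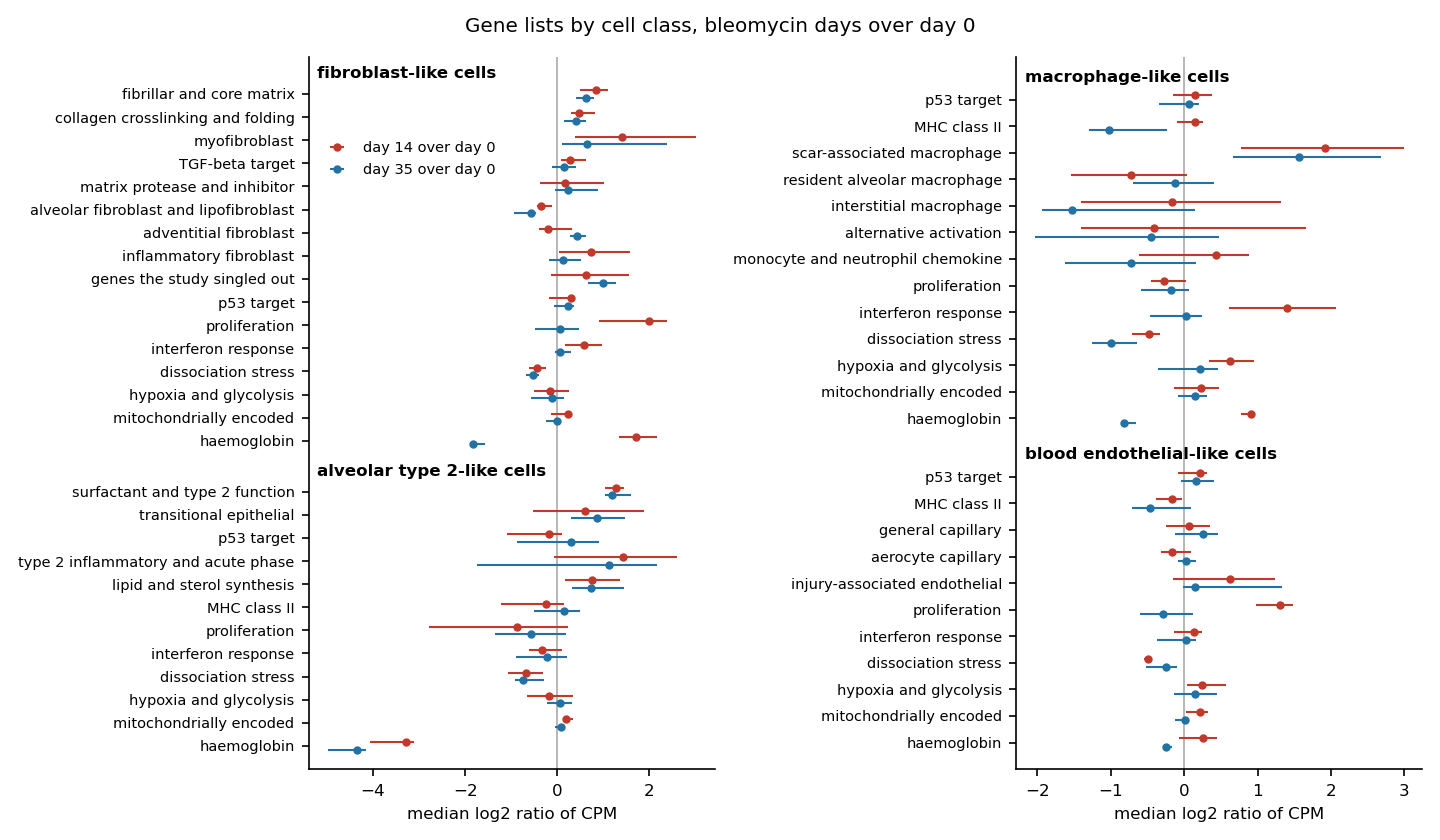
Median log2 ratio of each gene list with its interval over members, at day 14 over day 0 (red) and day 35 over day 0 (blue), in 4 classes. The scar-associated macrophage list stands at 1.92 and 1.57, and the fibrillar and core matrix list at 0.83 and 0.63.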

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

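All tests in this part were chosen after the results were seen, and the differences between days or classes were not tested.

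Haemoglobin transcripts drew attention because they moved in opposite directions over day 0, between the later days within 2 classes and between 2 classes at day 14. In fibroblast-like cells the list's median log2 ratio over day 0 was 1.72 at day 14 and -1.83 at day 35, a difference of 3.55. In macrophage-like cells it was 0.91 and -0.82, a difference of 1.73. At day 14 over day 0, fibroblast-like and alveolar type 2-like cells differed by 5.00, with 1.72 and -3.29. Of the alveolar type 2-like barcodes at day 0, 65 of 1195 were low-mixture. Effects of mixed RNA at day 0 therefore cannot be told apart from a difference between these 2 classes. Erythroid-like cells made up 0.189% of retained barcodes at day 0, 3.5% at day 14 and 0.983% at day 35. No explanation was tested for this pattern.

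Barcodes that no comparison used also carried a signal above a control level. Unnamed day 0 clusters held 16.9 UMIs of other lineages' genes per 1000, against 3.00 in B cell-like barcodes of the same library. The pattern weighed was that the 4 large clusters found almost only at day 0 carry RNA of several lineages. Free RNA alike in all droplets would add as many foreign UMIs to a B cell-like barcode, but the smallest ratio over the 4 clusters was 2.46. Multiplets of intact cells would hold more UMIs than single cells, but the clusters' median UMIs were at most 0.374 of those of low-mixture barcodes of the class whose markers they carry. Single cells that express several lineages would rarely hold both Xist and Y-linked transcripts, but 1343 barcodes did against 1432 expected if independent, a ratio of 0.938 (0.889 to 0.990). RNA released from broken cells of several mice and taken up in part of the day 0 suspension stays open as a candidate explanation, and so does a difference in how that library was handled or called.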

How the results depend on the processing

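Of 23 alternatives 22 were run, and 5 were chosen after seeing the data: naming clusters nearly all from 1 library, low-mixture barcodes, the share of named cells and each macrophage group alone. Leaving out GEM wells was not run because the barcodes show 1 well per library. No paired analysis was possible because the labels pair no samples, and no library could be left out with 1 per group. The cause was not tested for any change below except where stated.

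The 4 lists that answer the main comparisons kept their direction in each alternative that gave a value. Their medians ranged from 0.66 to 2.18 at day 14 over day 0 and 0.55 to 2.08 at day 35 over day 0 for core matrix, 0.19 to 0.68 and 0.37 to 1.04 for transitional epithelial, 1.52 to 2.12 and 1.41 to 2.01 for scar-associated macrophage, and 0.49 to 1.18 and 0.10 to 0.70 for injury-associated endothelial. At resolution 2.0 the cluster with alveolar type 2 markers stayed unnamed because 96.0% of its cells came from 1 library, past the limit of 95% set after the clusters were seen, so those lists have no value there. At resolution 1 that cluster stood at 94.4%.

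Naming by a marker score per cell gave core matrix medians of 1.42 and 1.30, fibroblast-like shares of 8.52% at day 0 and 2.66% at day 14, and turned 6 results. Alveolar fibroblast medians became 0.41 and 0.23, haemoglobin at day 14 over day 0 became -0.28 in fibroblast-like and -1.01 in macrophage-like cells, and log2 ratios at day 14 over day 0 became 0.62 for Cd248 and 0.54 for Pi16. Naming clusters nearly all from 1 library gave core matrix medians of 2.18 and 2.08, shares of 30.3% and 2.68%, alveolar fibroblast medians of 1.09 and 0.71, fibroblast-like haemoglobin of -0.41, Cd248 at 1.48 and Pi16 at 1.29. Low-mixture barcodes gave shares of 5.67% and 2.83%, surfactant medians of -0.18 and -0.0632, lipid synthesis medians of -0.14 and -0.28, endothelial MHC class II of 0.0157, and Csmd1 at day 35 over day 14 of 0.0251.

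Doublets kept turned endothelial MHC class II at day 14 over day 0 to 0.15, and haemoglobin at day 35 over day 0 to 0.33 in fibroblast-like and 0.25 in endothelial cells. Resolution 0.5 gave a day 0 fibroblast-like share of 1.23%, endothelial MHC class II of 0.0385 and macrophage haemoglobin at day 14 of -0.43. Resolution 2.0 gave a share of 1.83% and macrophage haemoglobin of -0.78. At most 5% mitochondrial UMIs gave shares of 1.59% and 2.69% and turned Cfd in endothelial cells at day 14 over day 0 to 1.62. As shares of named cells, the values were 4.53%, 2.76% and 2.93%, higher by construction. With named cells or low-mixture barcodes as the denominator, the day 0 share exceeded the day 14 share, so the direction of that share depends on the denominator. The interstitial cluster alone turned its own list at day 35 over day 14 to 0.0768 and macrophage haemoglobin at day 14 to -0.54. Thinning left 2 proliferation genes in fibroblast-like cells, with a median of -0.29.

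Over all reported values, 3908 of 5004 recomputed values stayed within the interval of the main value, 658 moved higher, 411 moved lower and 27 reversed. That interval covers counting error for shares and gene ratios, and the spread over members for list medians. Each naming change moved 53 of 198 gene ratios by over 1.5-fold. TMM scaling shifts all ratios of a class and comparison alike, and its largest factor, -0.28 log2, is below that limit. Its count of 0 was thus fixed in advance. By the interval, TMM scaling moved 65 of 340 values, 62 higher and 3 lower. Alveolar type 2-like values rest on 40 and 31 cells after bleomycin, and genes with few UMIs at day 0 have wide intervals.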

Other observations

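All tests in this part were chosen after the results were seen.

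Shares of other classes depended on whether unnamed barcodes were counted. Plasma cell-like cells, the antibody makers, made up 0.278% (0.231 to 0.332) at day 0, 1.63% (1.47 to 1.79) at day 14 and 0.294% (0.221 to 0.382) at day 35 among retained barcodes, but 0.891%, 1.86% and 0.321% of named cells. The plasma cell-like cluster held 122, 402 and 55 cells at resolution 1, of which 62, 216 and 43 were low-mixture. The named plasma cell-like cluster held 66, 86 and 38 cells at resolution 0.5 and 99, 79 and 33 at resolution 2. The size of the plasma cell-like peak at day 14 thus depended on the clustering resolution. Monocyte-like cells made up 0.991%, 5.87% and 5.46% of retained barcodes, neutrophil-like cells 3.23%, 6.29% and 4.96%, and NK cell-like cells 0.610%, 2.36% and 3.24%. Among named cells these were 3.18%, 6.73% and 5.97%, 10.4%, 7.21% and 5.42% and 1.96%, 2.70% and 3.54%. The lower neutrophil-like share after bleomycin among named cells is not a firm direction, since 560 of 1419 such barcodes at day 0 were low-mixture, against 1295 of 1555 at day 14. Smooth muscle-like cells made up 2.87%, 0.732% and 0.417%, and club-like cells of the airways 2.24%, 0.178% and 0.0908%. Of these, 179 of 1262 smooth muscle-like and 73 of 984 club-like barcodes at day 0 were low-mixture, against 171 of 181 and 40 of 44 at day 14, so the day 0 shares were mostly mixed barcodes. At day 0, Xist and Y-linked transcripts shared a barcode about as often as if independent in smooth muscle-like cells, at 0.991 (0.744 to 1.29), and in club-like cells, at 1.05 (0.781 to 1.37).

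The 10 genes with the largest falls in fibroblast-like cells at day 14, among them Muc13, Trim69 and Pde4c, came back in part at day 35, with a summed level of 922, 146 and 362 CPM in the 3 libraries, and the fall of Pde4c shrank to log2 ratios of -1.76 and -1.14 under the naming changes. A difference of equal size in every cell type is argued against by a ratio at day 14 over day 0 of 0.885 (0.796 to 0.985) in B cell-like cells and 0.159 (0.147 to 0.171) in fibroblast-like cells. However, the genes were chosen for their falls in the latter. The ratio was 0.255 in blood endothelial-like cells, where the genes rose 2.47-fold at day 35 over day 14, as in fibroblast-like cells. It was 0.376 (0.350 to 0.404) in macrophage-like and 0.693 (0.603 to 0.798) in T cell-like cells. At day 35 over day 14 the genes rose 1.37-fold and 1.65-fold in those classes and 1.36-fold in B cell-like cells. The median log2 ratio of the genes was -2.46 in low-mixture barcodes, against -2.44 over all fibroblast-like barcodes. Low-mixture barcodes were 544 of 621 such cells at day 0 and 584 of 596 at day 14. The subset was thus nearly the whole class, and it cannot decide whether RNA of other cells in day 0 barcodes played a part. Effects of differing stress in handling cannot be told apart from the pattern, since the stress list median was 0.00313 at day 35 over day 14, with 9 members higher and 9 lower, and -0.446 (-0.62 to -0.25) at day 14 over day 0. Time after injury may explain the pattern, as may RNA of other cells, differing stress or a library difference that varies in size by cell type. All stay open.

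The surfactant list was higher in alveolar type 2-like cells after bleomycin, with a median log2 ratio of 1.27 at day 14 over day 0. More free surfactant RNA after bleomycin is argued against by Sftpc in B cell-like cells, which stood at 0.22 of its day 0 level at day 14. RNA of other lineages in the day 0 barcodes is a candidate explanation, since the median was -0.183 among low-mixture barcodes. A change in the cells that survive injury stays open and was not tested apart from it.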
